A study of Mus musculus with 12 samples.

How the data were processed

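RNA from mouse livers was sequenced as total RNA after ribosomal RNA depletion, per the labels' protocols, in 12 libraries of tumour-bearing mice housed at 6, 22 or 29 °C (4 each, day 21). The authors deposited raw counts per gene, whole numbers without normalization, in 1 table of 55421 genes, with gene symbol, gene type and versioned Ensembl identifier per the file headers. The submitters' processing notes name bcl2fastq, STAR 2.6.1a, DESeq2 1.44.0 and the build GRCm38, with no role or order, and the counting program and its use of strand are not given in the sources used here. All 12 value columns were mapped to samples by the library name in each sample's description. Gene positions were taken from GENCODE vM21 (GRCm38) by identical identifier and version, which matched 54587 identifiers. 117 symbols occur more than once, and in gene lists the copy with the highest mean was used.

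Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust quasi-likelihood fit, two-sided tests). All 12 libraries entered a fit with 3 group means and 9 residual degrees of freedom, without covariates, since the labels name no batch. An adjusted p (Benjamini-Hochberg) under 0.05 was the threshold, with no minimum fold. 15006 genes were tested, with a common biological coefficient of variation of 0.321. Of 49 gene lists and marker sets written before the data were examined, the 46 with at least 3 measured genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. The mammary epithelial, pancreatic acinar and skeletal muscle markers had fewer and were not tested. With the correlation estimated from the data, no list call held in any of the 3 comparisons. Counts given as adjusted over the list alone were corrected within that list and not over the lists. Most of these lists were picked by their camera p in the same data, so such counts describe a list and are no separate support for it. Intestinal marker genes (20) were listed after Akp3 was seen in library 11 and before the others were looked up.

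Genes were named by a rule set before the data were examined. It took Fgf21, Cirbp and Rbm3 always, then the 5 highest and 5 lowest fold changes among called genes with a mean log2 CPM of at least 1, non-overlapping groups and a regular symbol, then up to 3 members with the lowest p in each of the 8 lists with the lowest camera p. Where the text says that genes were chosen under the split term, or after their values were seen, they fall outside this rule. Some genes that the rule names are not reported here. The split term is a covariate for the 4 libraries with at least 1 CPM of H2-Ea-ps. These libraries were set apart from the data, not from the labels, and they are not groups of the study. The growth protocol in the labels mentions both BALB/c and C57BL/6J mice without saying which library came from which strain.

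Total counts lay between 7615585 and 19001126. Counts were simulated with real library sizes and 100 genes changed per fold size. Each gene's mean was taken separately in the libraries with and without H2-Ea-ps counts, and dispersions came from the fit with the split term. Better recovery with the split term was therefore built in and does not speak for that fit. For 29 °C against 22 °C (14704 genes) the fit recovered 41% of 2-fold and 75% of 4-fold changes without the split term, and 56% and 86% with it. For 6 °C against 22 °C (14709 genes) the shares were 23% and 70% without it and 50% and 86% with it. For 29 °C against 6 °C (14694 genes) they were 37% and 74%, and 62% and 88%. False calls numbered 0 in each comparison without the split term, and 3, 5 and 3 with it, in the same order. Counts were drawn independently for each gene, with no structure between libraries besides the split. These false calls can therefore understate those in the real data. Every one of 18 replicate pairs differed by more than sampling noise (chi-square per degree of freedom 13.8 to 150), so none was treated as a repeat deposit.

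Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors, no low-count filter, a stricter filter, DESeq2 1.42.0, limma voom with quality weights, fits of the 8 libraries compared, a minimum absolute log2 fold change of 1, library sizes without mitochondrial and the 10 most abundant genes, camera with an estimated correlation, fry, and leaving out each library. Added after seeing the data were the split term, the split term without library 11, and the 8 libraries with no H2-Ea-ps counts. Exact permutation tests of Fgf21 used log2(CPM + 1), a pseudocount of 1.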

Results

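The data were total RNA profiles of livers from wild-type mice that carried E0771 tumours, a mouse mammary carcinoma line. The cells were placed in the mammary fat pad after 1 week of acclimatisation, and livers were taken on day 21. Mice were housed at 6 °C (libraries 1 to 4), 22 °C (libraries 5 to 8) or 29 °C (libraries 9 to 12), with 4 libraries per temperature. 22 °C is the usual animal room and 29 °C lies near thermoneutrality for a mouse. Total counts ran from 7615585 (library 2) to 19001126 (library 11), so that 3 counts in a library correspond to between 0.158 and 0.394 CPM, the usual count scaled by the library total. A level of 0 allows up to that value, for counting error alone. Of 55421 genes counted, 15006 passed the low-count filter. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries. Levels below are CPM on TMM-scaled library sizes, as mean ± SD over 4 libraries, and p-values are from edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment unless another test is named.

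Libraries did not group by housing temperature on the leading axis of variation. Libraries 1 (6 °C), 7 and 8 (22 °C) and 9 (29 °C) lay on one side of the first principal component, which held 39% of the variance, and the other 8 lay on the opposite side. The same 4 libraries held transcripts of H2-Ea-ps, a major histocompatibility class II gene that C57BL/6 mice do not transcribe, at 11.8 to 17.1 CPM of the total count, and the other 8 held 0 counts of it. They also held more mitochondrial ribosomal RNA, at 0.662% to 2.27% of counts against 0.0668% to 0.342% in the other 8. Ifi206, A730017L22Rik, Trim12a and Tafa2 had 0 counts in all 4 and at least 2.55 CPM in each of the other 8, and these genes were picked after their values were seen. Because the 4 libraries are spread unevenly over the temperatures (1, 2 and 1), each comparison is also given with this split of the libraries as a term in the fit, called the split term below and chosen after seeing the data. A further difference fell inside the 22 °C group: Gm26917, a ribosomal-RNA-related transcript, took 0.667% and 0.606% of counts in libraries 5 and 6, 1.66% in library 3 and 4.03% to 8.70% in the other 9.

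**Figure D1:**
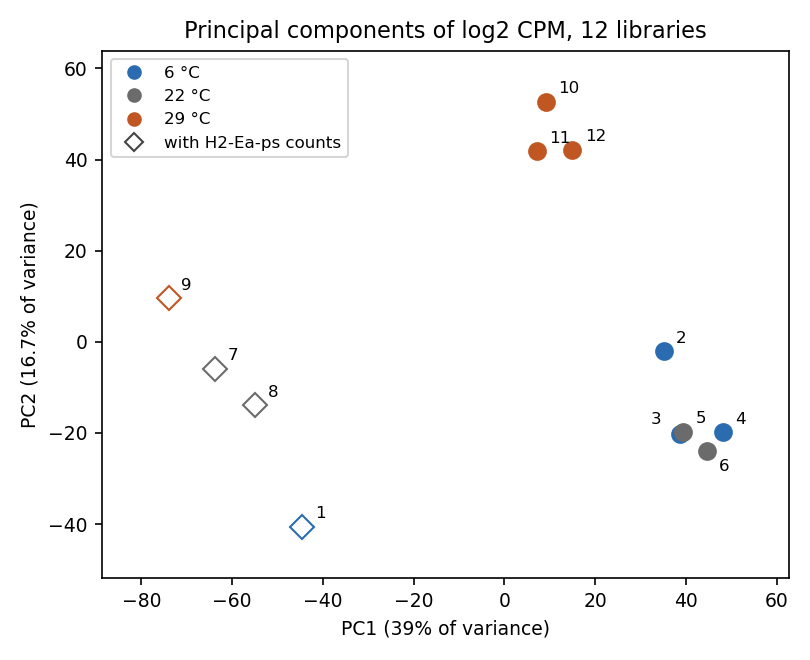
Principal components of log2 CPM over 15006 genes, with each point a library labelled by its number; colour gives housing temperature and open diamonds mark the 4 libraries with H2-Ea-ps counts. PC1 (39% of variance) parts these 4 from the other 8, and libraries 10 to 12 (29 °C) lie highest on PC2 (16.7%).

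The comparison of 29 °C with 6 °C spans the full range of housing temperatures. Fgf21, the fasting- and stress-induced liver hormone named in the title of the series, stood at 27.4 ± 12.5 CPM at 29 °C and 0.559 ± 0.697 CPM at 6 °C (n = 4 each). It rose by 5.45 on the log2 scale (SE 0.97, adjusted p = 0.0228), and 2 of the 6 °C libraries held 0 counts of it. An exact permutation test of log2(CPM + 1) gave p = 0.0286 (two-sided, n = 4 against 4), the smallest that 70 assignments allow. Fgf21 lies on chromosome 7 of GRCm38, from 45613886 to 45615490 on the minus strand (ENSMUSG00000030827.5). In all, 379 genes passed at an adjusted p under 0.05, of which 170 were higher and 209 lower at 29 °C. With the split term 1884 passed (949 higher, 935 lower), and all 379 were among them with the same direction. The count without the split term rests on few libraries: it was 41 without library 10, 71 without library 11, 149 without library 12, 211 without library 9, 67 without library 3 and 47 without library 4. The call of Fgf21 itself was lost without library 3 (adjusted p = 0.0707), 4 (0.0638), 10 (0.0734) or 11 (0.0522), and kept with the split term (5.82, adjusted p = 0.00470), within a range of 6.60e-05 to 0.0734 over the alternatives.

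Besides Fgf21, large rises at 29 °C over 6 °C among genes with no overlap between groups included Rgs16, Gadd45b and Angptl8. Rgs16, a regulator of G-protein signalling, stood at 211 ± 98.0 against 15.8 ± 11.2 CPM (log2 fold change 3.73, adjusted p = 0.00839). The stress gene Gadd45b rose by 3.56 and Angptl8, a feeding-responsive regulator of lipoprotein lipase, by 3.32 on the log2 scale. Non-overlapping groups were seen in 13.3% of tested genes, where random assignment of libraries gives 2.86% on average. Genes vary together, so a single assignment can lie far from that average. The share was not computed for other splits of the libraries, so no excess over chance is drawn from it. Among called genes with no overlap between groups and a mean log2 CPM of at least 1, the largest falls at 29 °C were in Upp2, Dio1, Mmd2, Cyp2a5 and Gas1. Dio1, the deiodinase that converts thyroxine to the active hormone and is itself induced by it, stood at 9.76 ± 4.17 CPM at 29 °C and 108 ± 30.8 CPM at 6 °C (log2 fold change -3.46, SE 0.36, adjusted p = 0.00156). Upp2, a uridine phosphorylase, stood at 30.5 ± 17.5 against 429 ± 182 CPM (log2 fold change -3.81, adjusted p = 0.0180). Mmd2 fell by 3.20 and Cyp2a5 by 2.34 on the log2 scale, and reads of Cyp2a5 may be shared with its close paralog Cyp2a4. Rgs16, Dio1 and Mmd2 passed under all 24 alternatives, while Gadd45b lost its call without library 3, 4 or 10, Upp2 and Gas1 without 4 or 10, Angptl8 without 1, 2, 4, 10, 11 or 12, and Cyp2a5 without 1, 3, 4, 9, 10 or 11. Angptl8 also lost it without a low-count filter, in the fit of the 8 libraries compared and in the 8 libraries with no H2-Ea-ps counts, and Cyp2a5 without a filter, in those 8 with no H2-Ea-ps counts and with the split term without library 11.

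Some genes of amino acid breakdown fell at 29 °C relative to 6 °C. Of 37 measured genes of the urea cycle and amino acid catabolism list, 7 fell, 0 rose and 30 did not pass, and 23 fell when adjusted over the list alone. Prodh, the proline dehydrogenase that starts proline breakdown, stood at 75.0 ± 15.7 against 233 ± 11.4 CPM (log2 fold change -1.64, SE 0.15, adjusted p = 0.000347). Tat and Tdo2, which start tyrosine and tryptophan breakdown, fell by 1.62 and 1.15 on the log2 scale. The list's median was -0.64 (camera adjusted p = 2.34e-17, and adjusted p = 0.301 with an estimated correlation). Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.48 over 58 genes, with 5 lower, 0 higher and 53 not passing, and 20 lower when adjusted over the list alone (camera adjusted p = 3.04e-15, and adjusted p = 0.207 with an estimated correlation). Ndufa4 fell by 0.60, Ndufs8 by 0.63 and Uqcr11 by 0.79 on the log2 scale. Xenobiotic metabolism had 2 of 28 genes lower, Sult1d1 (-1.09) and Cyp2a5, and 0 higher, or 6 lower when adjusted over the list alone (adjusted p = 4.72e-07, and adjusted p = 0.383 with an estimated correlation). In the cholesterol synthesis list 0 of 26 genes passed, over all genes or when adjusted over the list alone, and all 26 fold changes were negative (median -0.49, adjusted p = 5.80e-07, and adjusted p = 0.383 with an estimated correlation). Of the genes named here Prodh passed under all 24 alternatives, Sult1d1 lost its call without library 10, Tat without 3, 4, 10 or 12, Tdo2 and Ndufa4 without 3, 4, 9, 10 or 11, Ndufs8 without 1, 3, 4, 5, 9, 10, 11 or 12, and Uqcr11 without 2, 3, 4, 5, 9, 10, 11 or 12. Ndufs8 also lost it without a low-count filter, and Ndufa4, Ndufs8 and Uqcr11 lie under a minimum absolute log2 fold change of 1.

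Some glycolytic and immediate early genes, and 2 proliferation genes, rose at 29 °C relative to 6 °C. In the glycolysis list 5 of 21 genes rose and 0 fell, or 12 rose when adjusted over the list alone (median 0.86, adjusted p = 5.68e-08, and adjusted p = 0.198 with an estimated correlation). Gpi1, glucose-6-phosphate isomerase, stood at 349 ± 120 against 117 ± 12.9 CPM (log2 fold change 1.57, SE 0.22, adjusted p = 0.00677), and Aldoa and Hk1 rose by 0.86 and 1.03. Among 20 immediate early genes 5 rose and 0 fell, or 15 rose when adjusted over the list alone, with a median of 1.34 (adjusted p = 1.38e-15, and adjusted p = 0.207 with an estimated correlation). Jun stood at 160 ± 113 against 25.2 ± 6.30 CPM (log2 fold change 2.67), while Fosl2 rose by 1.01 and Ier3 by 1.64. Aurkb (2.04) and Mcm6 (1.00) rose among 30 proliferation genes, 28 did not pass and 6 rose when adjusted over the list alone. That list had a median of 1.10 (adjusted p = 3.37e-10, and adjusted p = 0.383 with an estimated correlation). Granulocyte precursor markers had a median of 2.10 over 12 genes, with Chil3 alone called (log2 fold change 2.24, adjusted p = 0.0213) over all genes or over the list alone (list adjusted p = 1.69e-07, and adjusted p = 0.382 with an estimated correlation). The precursor markers Fcnb and Ms4a3 were highest in library 9 among the 29 °C libraries, at 26.4 and 34.6 CPM, and library 9 is among the 4 that stand apart. Gpi1 passed under all 24 alternatives. Jun lost its call without library 3, 4 or 10, Chil3 without 3, 10 or 11, Aurkb without 2, 3, 4, 9, 10 or 11, Mcm6 without 2, 3, 4, 9, 10, 11 or 12, Hk1 without 2, 3, 4, 8, 9, 10, 11 or 12, Aldoa without 1, 2, 3, 4, 10, 11 or 12, and Fosl2 and Ier3 without 1, 3, 4, 9, 10, 11 or 12. Chil3 also lost it in the 8 libraries with no H2-Ea-ps counts and Hk1 under upper-quartile scaling, and Mcm6 and Aldoa lie under a minimum absolute log2 fold change of 1. Camera called 25 of 46 lists in this comparison. Library 11 also held intestinal transcripts, with 999 CPM over 20 intestinal markers against at most 279 CPM in the other 29 °C libraries.

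**Figure D2:**
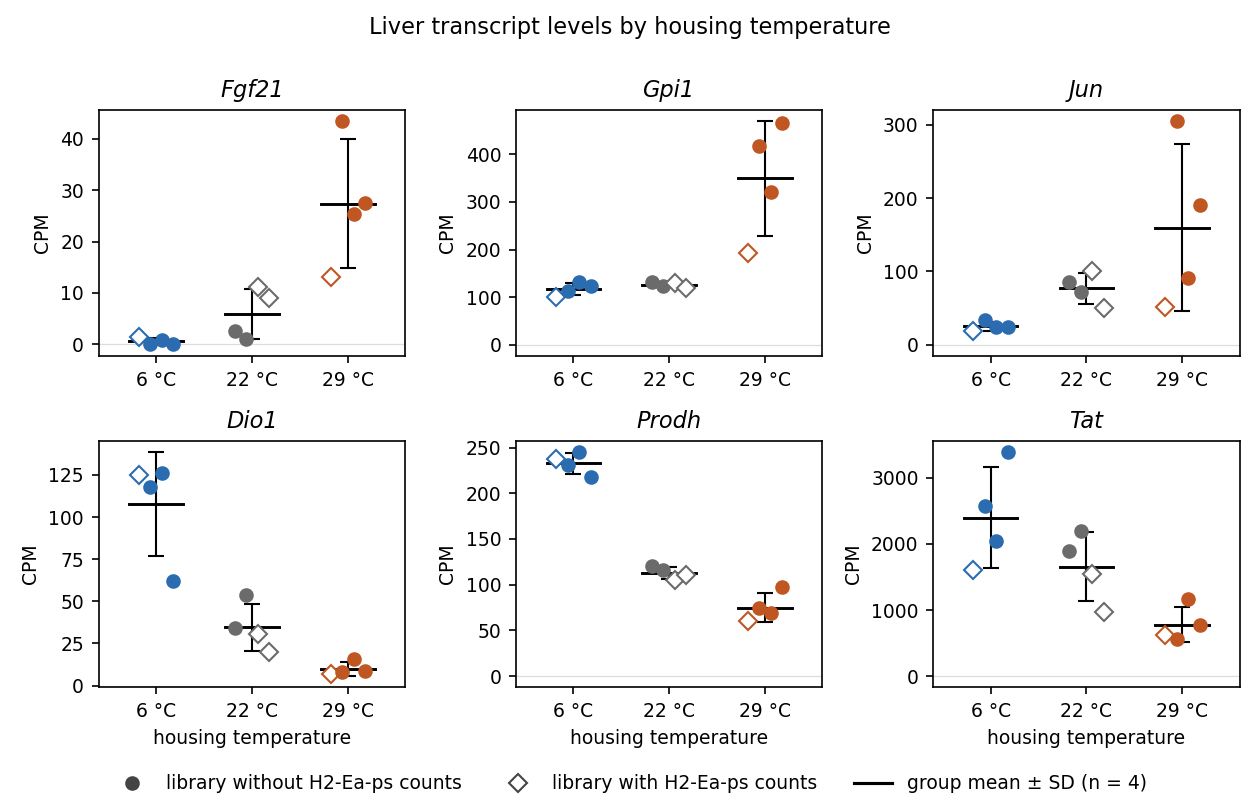
Levels (CPM, linear axes) of 6 genes against housing temperature, with 4 libraries per temperature, the bar at the group mean and the whisker ± SD; open diamonds are the 4 libraries with H2-Ea-ps counts. Fgf21 averages 0.559, 5.87 and 27.4 CPM and Prodh 233, 113 and 75.0 CPM at 6, 22 and 29 °C.

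The comparison of 29 °C with 22 °C sets near-thermoneutral housing against the usual animal room. Fgf21 stood at 27.4 ± 12.5 CPM at 29 °C and 5.87 ± 4.93 CPM at 22 °C (n = 4 each), with all 29 °C libraries above all 22 °C libraries. Its log2 fold change was 2.20 (SE 0.77), which did not pass over all genes (adjusted p = 0.248, or 0.0811 with the split term, within a range of 0.00917 to 0.540 over the alternatives). It passed in the 8 libraries with no H2-Ea-ps counts (log2 fold change 4.21, adjusted p = 0.00917). There the 22 °C group is libraries 5 and 6 alone, and 2594 of 15173 genes passed, so the pass is not particular to Fgf21. Within 22 °C it stood at 2.49 and 0.917 CPM in libraries 5 and 6 against 11.1 and 8.96 CPM in libraries 7 and 8, which are of the 4 that stand apart, and at 29 °C it was lowest in library 9 (13.1 CPM), which is of these 4 too. The exact permutation test for Fgf21 alone gave p = 0.0286 (two-sided, 4 against 4). edgeR called 0 genes in this comparison, with 2241 at an unadjusted p under 0.05, while DESeq2 called 325 and limma voom 5. With the split term, edgeR called 516 genes, 234 higher and 282 lower at 29 °C. That count was 100 without library 11. The count with 0 called became 78 without library 9 and 3 without library 7.

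Under the split term, a choice made after seeing the data, the genes with the largest rises and no overlap between groups included Tnfrsf12a, Acot2 and the haemoglobin gene Hba-a2. Tnfrsf12a, the receptor of the cytokine TWEAK, stood at 17.6 ± 6.18 against 3.21 ± 2.28 CPM (log2 fold change 2.73, SE 0.51, adjusted p = 0.0271 with the split term and 0.134 without it). Acot2, a mitochondrial acyl-CoA thioesterase, stood at 15.1 ± 5.79 against 4.02 ± 1.79 CPM (2.04 with the split term, adjusted p = 0.0216). Among the falls was Dio1, at 9.76 ± 4.17 against 34.6 ± 14.0 CPM (-1.89 with the split term, adjusted p = 0.0285). Uqcrb and Cox20, needed for respiratory complexes, had log2 fold changes of -1.40 and -1.32 with the split term. These follow libraries 5 and 6, the lowest in Gm26917: Uqcrb stood at 15.8 and 18.3 CPM there against 5.62 and 5.75 CPM in libraries 7 and 8, and Cox20 at 24.1 and 19.9 against 7.22 and 8.51 CPM. With the split term and no library 11, Hba-a2 (adjusted p = 0.0554), Uqcrb (0.0720) and Cox20 (0.0973) lost their calls, while Tnfrsf12a, Acot2 and Dio1 kept theirs. Adjusted p over the alternatives ranged from 0.000320 to 0.467 for Tnfrsf12a, 0.000354 to 0.466 for Acot2, 0.000158 to 0.467 for Dio1, 0.00117 to 0.467 for Hba-a2, 0.00136 to 0.467 for Uqcrb and 0.00118 to 0.473 for Cox20. Hba-a2 shares nearly all its sequence with Hba-a1, so the split of reads between them is uncertain. In this comparison 7.68% of genes had non-overlapping groups, where random assignment gives 2.86% on average. This share was not computed for other splits either, so it too cannot be weighed against chance.

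Among gene lists, glycolysis had the lowest camera p in the 29 °C against 22 °C comparison. Its median log2 fold change was 0.62 over 21 genes, 20 of them positive, with 0 called over all genes and 9 higher when adjusted over the list alone (camera adjusted p = 7.57e-10, and adjusted p = 0.0803 with an estimated correlation). Gpi1 stood at 349 ± 120 against 126 ± 5.72 CPM (log2 fold change 1.47, adjusted p = 0.0620, or 0.0181 with the split term) and Aldoa at 161 ± 28.5 against 83.1 ± 21.3 CPM. The lipid droplet and lipolysis list had a median of 0.43, with 0 of 20 called and 6 higher when adjusted over the list alone (adjusted p = 2.39e-07, and adjusted p = 0.204 with an estimated correlation). Plin2, a lipid droplet coat protein, stood at 656 ± 237 against 277 ± 66.4 CPM (adjusted p = 0.156, or 0.0454 with the split term and 0.0700 with it and no library 11), and Cidec, a droplet fusion protein, at 3.33 ± 0.892 against 0.448 ± 0.533 CPM. For 43 PPARA target and fatty acid oxidation genes the median was 0.35, with 0 called and 3 higher when adjusted over the list alone (adjusted p = 1.98e-06, and adjusted p = 0.709 with an estimated correlation). Immediate early genes had a median of 0.77 with 0 of 20 called and 5 higher when adjusted over the list alone (adjusted p = 9.85e-07, and adjusted p = 0.561 with an estimated correlation), among them Klf4 at 10.5 ± 3.79 against 3.99 ± 0.997 CPM. Adjusted p over the alternatives lay between 7.92e-07 and 0.261 for Gpi1 and between 0.00281 and 0.467 for Plin2.

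Of lists with a negative median at 29 °C against 22 °C, the 7 measured mitochondrially encoded mRNAs had the lowest camera p. Their median log2 fold change was -1.28, all 7 were negative, and 0 were called over all genes and 7 when adjusted over the list alone (adjusted p = 6.09e-07, and adjusted p = 0.339 with an estimated correlation). mt-Co1 stood at 5650 ± 485 against 14300 ± 8800 CPM, and at 20400 and 23300 CPM in libraries 5 and 6 against 6130 and 7480 CPM in libraries 7 and 8. Libraries 5 and 6, with library 3 (17500 CPM), are also the lowest in Gm26917. Among cell markers, erythroid genes had a median of 0.96 over 13 genes (0 called, 5 higher when adjusted over the list alone, adjusted p = 2.99e-06, and adjusted p = 0.519 with an estimated correlation). The erythroid median was 0.41 with the split term. Kupffer cell and macrophage markers had a median of 0.51 over 18 genes, with 0 called and C1qc higher when adjusted over the list alone (adjusted p = 1.69e-05, and adjusted p = 0.760 with an estimated correlation). C1qc stood at 65.2 ± 17.9 against 31.7 ± 7.82 CPM. Cytosolic ribosomal protein genes had a median of 0.27 over 69 genes, with 0 called and 7 higher when adjusted over the list alone (adjusted p = 0.000109, and adjusted p = 0.0803 with an estimated correlation), and many have processed pseudogenes that can share their reads. Camera called 19 of 46 lists here.

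Housing at 6 °C was compared with 22 °C to ask what cold exposure changes. 5 genes passed, of which 3 were higher and 2 lower at 6 °C, and 1787 genes had an unadjusted p under 0.05. Hes6, a transcriptional regulator of the Hes family, stood at 33.9 ± 9.01 CPM at 6 °C and 8.81 ± 1.61 at 22 °C (log2 fold change 1.94, SE 0.21, adjusted p = 0.00319). Its level did not follow temperature in order: at 29 °C it was 15.8 ± 1.69 CPM, with libraries at 14.8 to 18.4 against 7.66 to 11.2 CPM at 22 °C. Prodh stood at 233 ± 11.4 against 113 ± 6.43 CPM (1.04, SE 0.15, adjusted p = 0.0242) and Mmd2 at 46.8 ± 31.7 against 6.42 ± 1.01 CPM (2.86, SE 0.41, adjusted p = 0.0361). Inhba, the activin A subunit, fell from 33.2 ± 2.74 to 10.9 ± 3.56 CPM (-1.61, SE 0.21, adjusted p = 0.00959). The non-coding RNA Hectd2os stood at 5.78 ± 1.38 against 24.3 ± 5.92 CPM (-2.08, adjusted p = 0.00319), and its reads cannot be told from those of a gene on the opposite strand, since strand use in counting is not given in the sources used here. With the split term 55 genes passed (29 higher, 26 lower), all 5 included, and Fgf21 did not pass in any form of this comparison that was run (log2 fold change -3.25, adjusted p = 0.268). The 5 became 3 without library 2, 5, 6, 8, 10 or 11: Hes6 and Hectd2os passed under all 24 alternatives and Inhba whichever library was left out, while Prodh lost its call without library 1, 2, 3, 4, 5, 6, 7, 8, 10 or 11 and Mmd2 without 2, 5, 6, 7, 8, 10 or 11. Inhba and Mmd2 also lost theirs in the fit of the 8 libraries compared, and Mmd2 with limma voom, without a low-count filter, in the 8 libraries with no H2-Ea-ps counts and with the split term without library 11. DESeq2 called 178 and limma voom 4.

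The leading lists of the 6 °C and 22 °C comparison were oxidative phosphorylation, amino acid catabolism and cholesterol synthesis, with positive medians at 6 °C. Nuclear-encoded oxidative phosphorylation genes had a median of 0.42, with 52 of 58 positive, 0 called and 12 higher when adjusted over the list alone (camera adjusted p = 2.08e-15, and adjusted p = 0.616 with an estimated correlation). Ndufb8 stood at 36.1 ± 2.89 against 22.7 ± 4.71 CPM and Sdhb at 102 ± 29.0 against 56.9 ± 9.35 CPM. In urea cycle and amino acid catabolism all 37 fold changes were positive (median 0.49), 1 gene rose (Prodh) and 8 rose when adjusted over the list alone (adjusted p = 2.92e-13, and adjusted p = 0.616 with an estimated correlation). All 26 cholesterol synthesis genes were positive as well (median 0.61), with 0 called and 8 higher when adjusted over the list alone (adjusted p = 6.22e-13, and adjusted p = 0.616 with an estimated correlation). Dhcr7 stood at 184 ± 20.8 against 110 ± 10.4 CPM. De novo lipogenesis had a median of 0.37 over 25 genes, with 0 called and 4 higher when adjusted over the list alone (adjusted p = 4.74e-06, and adjusted p = 0.616 with an estimated correlation). Aacs, acetoacetyl-CoA synthetase, stood at 85.2 ± 13.7 against 39.7 ± 6.90 CPM (adjusted p = 0.0980, or 0.0259 with the split term, within a range of 0.000121 to 0.352). This was not particular to 6 °C, as Aacs stood at 90.7 ± 20.4 CPM at 29 °C. The lipogenesis list also had a positive median at 29 °C against 22 °C (0.29, camera adjusted p = 0.000776, and adjusted p = 0.760 with an estimated correlation). With the split term camera did not call the list there (adjusted p = 0.0647), while it did for 6 °C against 22 °C (adjusted p = 0.000364). Camera did not call the lipogenesis list for 29 °C against 6 °C (adjusted p = 0.511).

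Lists with a negative median at 6 °C included proliferation, with all 30 fold changes negative, a median of -0.82 and 0 called over all genes or over the list alone (adjusted p = 1.91e-07, and adjusted p = 0.730 with an estimated correlation). Its median was -0.44 with the split term, where 28 of 30 were negative, and Aurkb stood at 8.24 and 6.50 CPM in libraries 7 and 8, of the 4 that stand apart, against 3.05 and 3.16 CPM in libraries 5 and 6. Immediate early genes had a median of -0.71 with 0 of 20 called either way (adjusted p = 9.72e-06, and adjusted p = 0.639 with an estimated correlation), Jun among them at 25.2 ± 6.30 against 77.2 ± 21.2 CPM. All 18 neutrophil markers (median -0.59, adjusted p = 2.09e-05, and adjusted p = 0.730 with an estimated correlation) and all 12 granulocyte precursor markers (median -1.58, adjusted p = 3.16e-05, and adjusted p = 0.730 with an estimated correlation) had negative fold changes, with 0 called over all genes or over either list alone. Some of these transcripts move with the 4 libraries that stand apart, of which the 22 °C group has 2 and the 6 °C group 1: Camp stood at 46.7 and 45.5 CPM in libraries 7 and 8 against 9.41 and 7.94 CPM in libraries 5 and 6, and at 22.8 CPM in library 1 against 0.836 to 4.85 CPM in the other 6 °C libraries. These medians were -0.41 and -1.08 with the split term. Camera called 14 of 46 lists. Gene lists and their medians for the 3 comparisons are plotted together.

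**Figure D3:**
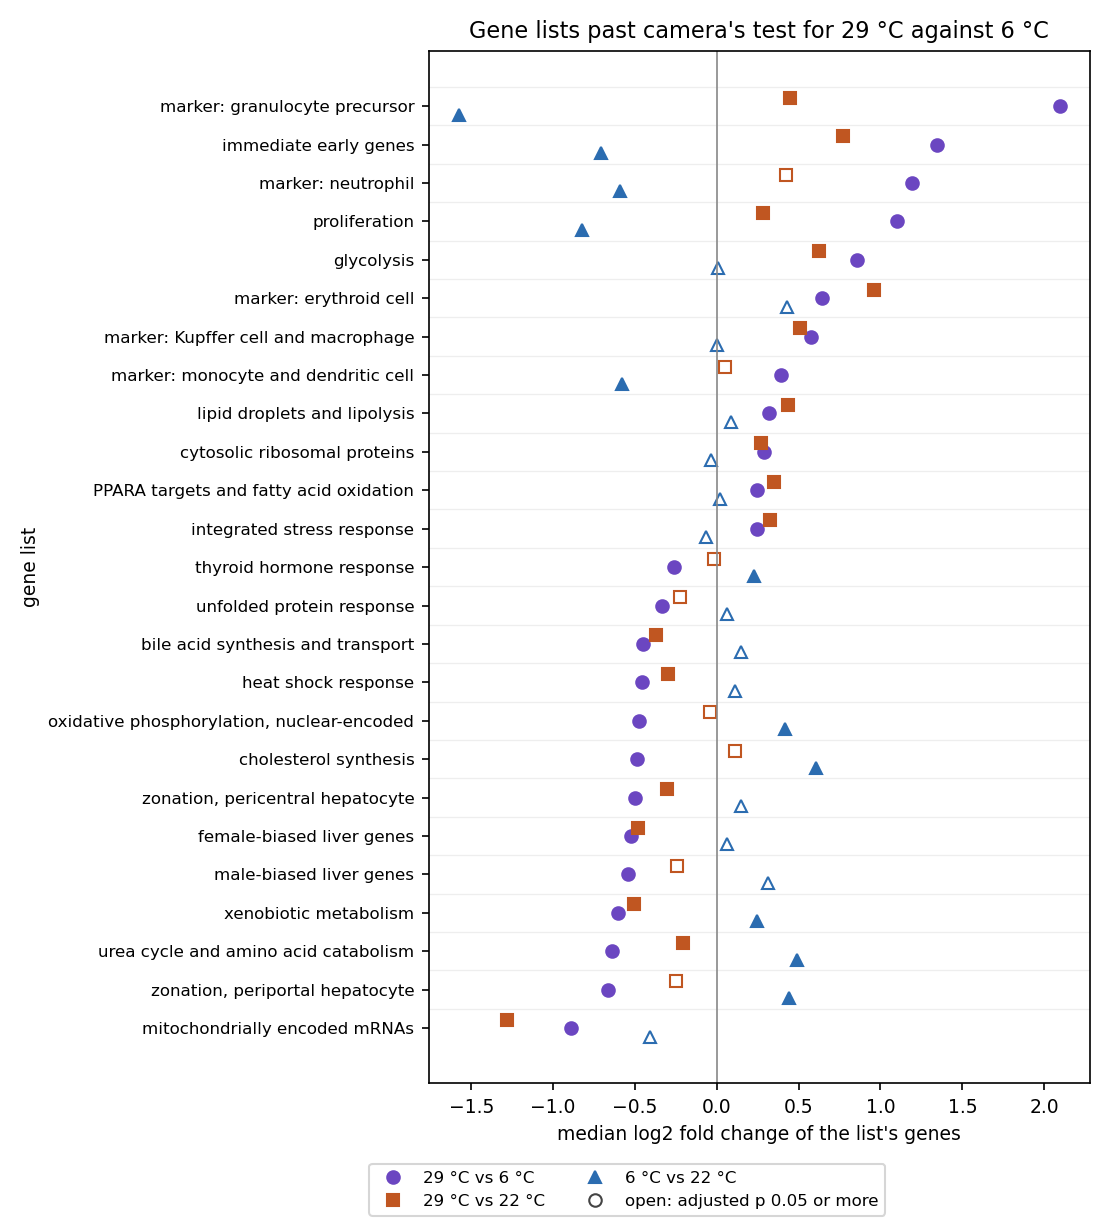
Median log2 fold change (horizontal axis) of each of the 25 gene lists called by camera for 29 °C against 6 °C (circles), with the same lists for 29 °C against 22 °C (squares) and 6 °C against 22 °C (triangles); filled symbols have an adjusted p under 0.05 at the preset correlation. Granulocyte precursor markers lie at 2.10 and mitochondrially encoded mRNAs at -0.89 for 29 °C against 6 °C.

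Over the 3 temperatures jointly, 100 genes differed, with 2945 at an unadjusted p under 0.05. The cold-inducible RNA-binding protein genes were not called by temperature: Cirbp stood at 8.90 ± 1.18, 7.29 ± 4.0 and 9.61 ± 2.68 CPM at 6, 22 and 29 °C, and Rbm3 at 12.3 ± 5.38, 12.4 ± 5.21 and 16.4 ± 8.53 CPM. Neither passed in the 3 pairwise comparisons, the lowest adjusted p being 0.602 for Cirbp at 29 °C against 22 °C. In that comparison Cirbp passed in the 8 libraries with no H2-Ea-ps counts (log2 fold change 1.04, adjusted p = 0.0377), within a range of adjusted p up to 0.851 over the alternatives. The count of 100 was 55 without library 2, 23 without 3, 33 without 4, 34 without 5, 58 without 6, 151 without 7, 55 without 8, 196 without 9, 8 without 10, 25 without 11 and 8 without 12. Without the 4 libraries that stand apart, which leaves 3, 2 and 3 libraries and was chosen after seeing the data, 2594 genes passed for 29 °C against 22 °C, 1015 for 6 °C against 22 °C and 1504 for 29 °C against 6 °C. The 22 °C group is then libraries 5 and 6 alone, which are the 2 with the lowest Gm26917 share.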

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

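The tests below of RNA quality, cell mixture, the split term, both backgrounds and intestinal tissue were chosen after the results they bear on were seen, while those of gene clustering, of Fgf21 without library 11 and of other splits of the libraries were set before. Across 285 groups of 4 libraries, 22 had a library far from the other 3 (7.72%). The rule flags about 1 in 20 groups when values are normal and independent. These CPM values are neither: 9 of the 22 fell on library 9, and H2-Ea-ps, by which 4 libraries were set apart, is among them. The share of 7.72% therefore cannot be weighed against 1 in 20.

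Libraries 1, 7, 8 and 9 stand apart from the other 8: H2-Ea-ps was at 17.1 CPM in library 1 and 11.8 CPM in library 9 and at 0 in the other libraries of their groups, and the mitochondrial rRNA share reached 2.27% in library 1 and 0.843% in library 9. Lower RNA quality is argued against by 6 genes, not counting H2-Ea-ps by which the 4 were set apart, with 0 counts in all of the other 8 libraries and at least 2 CPM in each of these 4, since loss of RNA adds no gene, but the 4 genes lost in them leave it open for lower levels. Another cell mixture is argued against by 10 genes with a mean of 50 CPM or more in the other 8 that are at least 8-fold lower in the 4, among them the hepatocyte genes Serpina1d and Cyp2c23, while the albumin share was 6.21% to 6.72% in the 4 and 6.10% to 14.6% in the other 8; some of the 10, such as Cyp4a14, also vary between temperatures. Another genetic background is a candidate explanation: 11 genes, H2-Ea-ps included, were present in all libraries of one set and absent from the other, while none of the other splits of 4 against 8 libraries gave any (highest 0 of 495 splits counted with this one). Only 20% of these genes had another within 1 Mb, within the range of random draws (up to 40%, and 7.10% of 1000 draws reached it), but 10 genes with a position are too few for that bound, and the labels cannot settle it.

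Fgf21 was higher at 29 °C than at 6 °C, and so it was in 10 of 10 pairs of libraries from the same set, where no pair could have come out otherwise because the groups do not overlap. Among the 8 libraries with no H2-Ea-ps counts, 3 at each of both temperatures, the difference passed (log2 fold change 6.67, adjusted p = 0.00353, within a range of 6.60e-05 to 0.0734 over the alternatives), while the other set holds 1 library at each and leaves an effect of housing temperature there untested. The split of the libraries could not give this difference by uneven spread, since each of the temperatures holds 1 library with H2-Ea-ps counts and 3 without. The adjusted p of 0.00470 with the split as a term adds nothing to that, because a balanced term leaves such a difference in place. Intestinal RNA in library 11 is argued against as the cause, since the log2 fold change was 5.49 without it and 5.45 (SE 0.97) with it. Without library 11 the adjusted p rose to 0.0522 with fewer libraries. Differences in food intake or tumour size between temperatures were not analysed here and stay open.

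In library 11 (29 °C), 20 intestinal marker genes summed to 999 CPM, with the other 29 °C libraries between 253 and 279 CPM. 15 of the 20 were more than 4-fold above the highest of the other 11 libraries, or 12 when 0 is replaced by the level of 3 counts (0.394 CPM), and 4 of the 20 are also at a median of 1 CPM or more in the other libraries. Akp3 stood at 290 CPM, Slc5a1 at 91.9, Sis at 75.3 and Muc2 at 53.2 CPM, while Anpep, which liver makes itself, was not raised (226 CPM). Intestinal tissue in the piece is a candidate source, and no biological explanation was tested.

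Among other genes, library 9 (29 °C) stood far above the rest of its group in neutrophil and precursor transcripts: Stfa2l1 was at 8.03, Camp at 87.5, Ly6g at 12.4, Fcnb at 26.4 and Ms4a3 at 34.6 CPM. It was also high in mt-Cytb (3900 CPM) and Trpm6 (4.48 CPM). In the 22 °C group, library 8 was apart in Hbb-bt (3.29 CPM, low), Mmd2 (7.91 CPM) and Hes6 (11.2 CPM), and library 7 in Dhcr7 (95.0 CPM, low) and Stfa2l1 (15.4 CPM). Library 4 (6 °C) had Dio1 at 61.8 CPM against 118 to 126 CPM in its group. Library 10 (29 °C) had St6galnac4 at 11.1 CPM, and library 11 had Hes6 at 18.4 CPM and Ndufs8 at 15.2 CPM. Library 2 (6 °C) was the shallowest, at 7.62 M counts against 12.6 to 13.3 M in its group.

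Other splits of the libraries were used to ask whether chance can be excluded. The counts argue against chance for 29 °C against 6 °C (379 genes, 1 of 35 splits as large, highest other 0). They do so for the 3 temperatures jointly as well (100 genes, 1 of 100 drawn, highest other 1). For 6 °C against 22 °C chance is not excluded (5 genes, 1 of 35, highest other 2). There 1 of 35 is the smallest share possible, the margin is small, and with the split term another split gave more genes than the real one. For 29 °C against 22 °C without the split term the count was 0, so that 35 of 35 splits gave as many by construction (highest other 1), which says nothing about chance. With the split term and splits within each set, the count argues against chance for 29 °C against 22 °C (516 genes, 1 of 30, highest other 3). It was 100 without library 11. Among libraries with no H2-Ea-ps counts the 22 °C group is 5 and 6, the lowest in Gm26917, so these splits cannot part that structure from temperature. For 6 °C against 22 °C chance cannot be excluded (55 genes, 2 of 30). The split that puts libraries 1, 3, 5 and 6 together gave 181, several times the real count, which points to a structure of the samples. That split sets together libraries 3, 5 and 6, the lowest in Gm26917. For 29 °C against 6 °C with the split term, 20 splits are too few for a share under 0.05 (1884 genes, 1 split as large, highest other 0). Counts of gene lists did not exclude chance: 19 lists for 29 °C against 22 °C (18 of 35 splits, highest other 28), 14 for 6 °C against 22 °C (27 of 35, highest other 25) and 25 for 29 °C against 6 °C (7 of 35, highest other 30).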

How the results depend on the processing

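The split term, the split term without library 11, and the 8 libraries with no H2-Ea-ps counts were chosen after the data were seen; all other alternatives were set before. Counts of genes are given in the order 29 °C against 22 °C, 6 °C against 22 °C, 29 °C against 6 °C and any difference, and were 0, 5, 379 and 100. DESeq2 gave 325, 178, 1196 and 1196. With the split term they were 516, 55, 1884 and 1681, with the split term and no library 11 100, 36, 1305 and 957, and in the 8 libraries with no H2-Ea-ps counts 2594, 1015, 1504 and 3278. limma voom gave 5, 4, 1090 and 247. Without a low-count filter 15 and 225 genes passed for 29 °C against 22 °C and any difference. A minimum absolute log2 fold change of 1 left 196 for 29 °C against 6 °C, and the fit of the 8 libraries compared left 3 for 6 °C against 22 °C. The cause of these shifts was not tested, except that a minimum fold removes genes by construction. Size factors, upper-quartile scaling, the stricter filter and the trimmed library sizes kept all counts that they gave within 1.5 times.

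Leaving out each library in turn gave 0 to 78, 3 to 7, 41 to 439 and 8 to 196 genes. The highest of these were without library 9 (78), 9 (7), 7 (439) and 9 (196). For gene lists, calls ranged over 12 to 21, 11 to 21 and 22 to 26 in the 3 pairwise comparisons, the 12 being without library 5 in 29 °C against 22 °C. With an estimated correlation camera called 0, 0 and 0 of the 19, 14 and 25 lists, and 0 in each with the split term as well; fry called 3, 0 and 5. In the 8 libraries with no H2-Ea-ps counts 9 lists were called for 6 °C against 22 °C. For named genes, 31 called values had 744 alternatives, of which 602 stayed called in the same direction, 142 lost the call and 0 reversed. The 78 values not called had 1870, of which 185 passed the threshold in the same direction and 0 in the opposite one. A change of sign was not counted where neither the main fit nor the alternative called the gene. Such changes occurred: Rbm3 at 6 °C against 22 °C ran from -0.359 to 0.315 on the log2 scale. Fgf21 at 29 °C against 6 °C lost its call without library 3 (adjusted p = 0.0707), 4 (0.0638), 10 (0.0734) or 11 (0.0522). Depth limits genes near 0: a level of 0 allows up to 0.158 to 0.394 CPM.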

Other observations

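Several groups not described above also passed camera for 29 °C against 6 °C, and the members named here were chosen after their values were seen. Bile acid synthesis and transport had 3 of 24 genes lower, Cyp7b1, Cyp2c70 and Abcg5, and 0 higher, or 7 lower when adjusted over the list alone (median -0.45, camera adjusted p = 0.000176, and adjusted p = 0.382 with an estimated correlation). In the lipid droplet and lipolysis list, with 12 positive and 8 negative fold changes, Plin2, Plin5, G0s2 and Hilpda rose by 1.77, 1.58, 2.80 and 2.89 on the log2 scale, 4 of 20 genes in all, or 8 higher and 1 lower when adjusted over the list alone (median 0.32, adjusted p = 0.00102, and adjusted p = 0.382 with an estimated correlation). PPARA target and fatty acid oxidation genes had 3 of 43 higher, Acot2 (2.41), Crat (1.30) and Pex11a (0.98), or 6 higher when adjusted over the list alone, with a median of 0.25 (adjusted p = 8.84e-06, and adjusted p = 0.383 with an estimated correlation). Among hepatokines, a list that camera did not call (adjusted p = 0.113), Inhba rose by 2.23 (adjusted p = 0.000347). The thyroid hormone response list passed camera (median -0.26, adjusted p = 0.00376, and adjusted p = 0.383 with an estimated correlation) with Dio1 lower and Gpd2 higher by 0.76, so its called members moved apart (1 higher and 3 lower when adjusted over the list alone). Male-biased liver genes had 3 of 16 lower, Mup16, Nudt7 and Cyp7b1, over all genes and when adjusted over the list alone (median -0.54, adjusted p = 0.0481, and adjusted p = 0.382 with an estimated correlation), and reads of Mup16 cannot be told from its many near-identical copies. Female-biased liver genes had a negative median as well (-0.53, with 21 of 25 fold changes negative). Of these 0 were called over all genes and 1 was lower when adjusted over the list alone. Camera gave an adjusted p = 0.00867 for them, and adjusted p = 0.478 with an estimated correlation. A negative median was thus not particular to male-biased genes. In the heat shock list Hspd1 fell by 0.47 and 19 of 20 did not pass, with 3 lower when adjusted over the list alone (median -0.46, adjusted p = 0.000215, and adjusted p = 0.383 with an estimated correlation).

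Markers of blood and immune cells also passed camera for 29 °C against 6 °C, with positive medians. Neutrophil markers had a median of 1.19 with 17 of 18 positive. None was called over all genes or when adjusted over the list alone (adjusted p = 8.14e-07, and adjusted p = 0.383 with an estimated correlation). Library 9 held the most Camp (87.5 CPM). Kupffer cell and macrophage markers had 18 of 18 positive (median 0.58) and erythroid markers 12 of 13 (median 0.64). Over all genes, or when adjusted over either list alone, 0 were called (adjusted p = 0.000275 and 0.0136, and adjusted p = 0.478 and 0.497 with an estimated correlation). Monocyte and dendritic cell markers had 1 of 15 higher, Chil3, or 2 when adjusted over the list alone (median 0.39, adjusted p = 0.00228, and adjusted p = 0.382 with an estimated correlation). Pericentral hepatocyte genes had a median of -0.50 over 16 genes. Oat was lower and Tbx3 higher, or 4 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00130, and adjusted p = 0.383 with an estimated correlation). Periportal genes had a median of -0.66 over 17 genes. Of these 0 were called, and 3 were lower when adjusted over the list alone (adjusted p = 0.00228, and adjusted p = 0.466 with an estimated correlation).

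For 6 °C against 22 °C the circadian clock list passed camera, with 0 of 20 genes called and 6 higher when adjusted over the list alone (median 0.47, adjusted p = 0.0221, and adjusted p = 0.616 with an estimated correlation). The lists for interferon response, glucocorticoid response, p53 targets, glycogen metabolism, lipoproteins, acute phase response and hepatocyte markers were not called by camera in any of the 3 pairwise comparisons. Their smallest adjusted p at the preset correlation was 0.175, for hepatocyte markers at 29 °C against 6 °C. The markers of T and NK cells, B and plasma cells, endothelial cells, stellate cells, cholangiocytes and adipocytes were not called either.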
